A study of Rattus norvegicus with 6 samples.

How the data were processed

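Dorsal root ganglia were profiled in 6 male Sprague-Dawley rats, 3 diabetic and 3 control, on 1 Affymetrix rat transcriptome array (RTA 1.0) per rat. Per the labels' protocols, rats of 180 to 220 g were assigned at random, the diabetic group was given 1 intraperitoneal dose of 65 mg/kg streptozotocin, a toxin that destroys the insulin-producing beta cells of the pancreas, and the control group citrate buffer. Treated rats below 16.7 mM non-fasting blood glucose 1 week later were excluded, and ganglia from the lumbar levels of both sides were taken 8 weeks after the injection and pooled within each rat. Biotinylated cDNA was made from 100 ng of total RNA. Each array is therefore a separate animal.

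The deposited values are log2 signals per transcript cluster, which the column names of the file describe as gene-level SST-RMA (signal space transformation followed by robust multi-array averaging), and RMA is also named in the submitters' processing notes without a version. RMA subtracts background, makes the distribution of probe signals equal between arrays and summarises the probes of a cluster on the log2 scale. It can compress differences of dim clusters towards 0, so a fold change of a dim cluster may understate the change. Genome build and software version are not given in the sources used here, and the unplaced contig names are those of the rat assembly rn6, so coordinates are given as the deposited annotation lists them. The series matrix and the annotated table held the same numbers, with 0 cells differing. The 6 columns of detection calls were not used, because all 423480 calls read absent.

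The annotated table holds 70580 probe sets. The 1738 control probe sets, among them 1153 intron and 399 exon controls, were left out of all tests, which leaves 68842 transcript clusters: 24753 coding, 25625 non-coding, 10838 unassigned and the rest of smaller classes, by the deposited class column. No filter on dim clusters was used. Symbols were taken from the deposited annotation, 64912 clusters having 1 symbol, and 2421 older symbols were updated through the gene table of the rat assembly GRCr8, used for names only. The depth of an array is its signal over background, and the number of arrays limits the precision of every comparison. Spread is given as SD over the 3 arrays of a group, and SE is that of the fitted difference.

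Diabetic minus control was tested with limma (version 3.58.1 in R 4.3.3): a linear model with the group as its only term, eBayes with an intensity trend, and Benjamini-Hochberg adjustment over all 68842 clusters, with a threshold of 0.05. A looser count took clusters with an unadjusted p under 0.05 and at least a 1.5-fold difference of means. An exact permutation test of 3 against 3 animals cannot go below a two-sided p of 0.1, so it was not used for single genes. The fit was tested on simulated data with each cluster's spread in these arrays, the noise being independent between clusters and arrays. In each run 200 of the 68842 clusters were changed. The fit recovered 60.0% of changes of 1 log2 unit with 3 false calls. It recovered 96.5% of changes of 2 units with 8 false calls and 98.5% of changes of 3 units with 5. The changed clusters were drawn at random from all clusters, so these shares are averages that a cluster of larger spread need not reach. In the real arrays Pmp2, at a log2 fold change of -2.42, did not pass (limma adjusted p = 0.50).

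The 46 gene lists (cell types, channels, metabolism, stress, signalling and states) were written before the data were examined, as were the tests, the thresholds and the alternatives, apart from those the closing section names. Of 1146 listed symbols, 1104 are on the array, and a gene was represented by its cluster of highest mean. Lists were tested with limma's camera, which compares a list with all other symbols, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 46 lists. The correlation estimated per list, and fry, which does not compare a list with other genes, were alternatives. On simulated data with independent noise, a shifted list was called by camera with the preset and with the estimated correlation, and 0 other lists were. Genes of a simulated list were not correlated, so the simulation cannot check the preset correlation for real lists, whose genes are. Members were also counted past adjusted p 0.05 over the list alone.

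The genes named were fixed by a rule. It takes the 12 coding clusters with 1 symbol that changed most in each direction among those past adjusted p 0.05 with no overlap between the groups' arrays, filled up by the smallest unadjusted p among clusters of at least 1.5-fold without overlap, and 5 non-coding clusters per direction by the same steps. It adds up to 4 members of each list with the smallest p, the 2 members of highest mean of each cell type list, and 14 genes in any case, among them Ins1, Ins2, Slc2a4, Txnip, Calca, Tac1, Scn9a, Scn10a, Trpv1, Atf3, Gal, Npy and Nefh. Other genes named were chosen after their values were seen. Predicted genes and identifiers count as symbols.

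The share of coding and of non-coding clusters past the looser criterion was compared by Fisher's exact test, two-sided, over clusters, which are not independent, and within 3 bands of mean level holding equal numbers of clusters. Each non-coding cluster was paired with its nearest coding cluster within 10 kb by the deposited coordinates (GenomicRanges 1.54.1), and Spearman's rho of the fold changes across pairs was set against 10000 random pairings, in 6 relations by overlap and strand with Benjamini-Hochberg adjustment over them. Alternatives were eBayes without the trend or with robust estimation, no moderation of the variance, array weights, a filter at the median level, quantile normalization again, median centring, the series matrix values, the replicate number as a block, other thresholds, distances and list tests, and each array left out in turn.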

Results

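Dorsal root ganglia hold the cell bodies of sensory neurons with the satellite and Schwann cells around them, and diabetes is known to damage these neurons. RNA of lumbar ganglia was compared between 3 diabetic rats and 3 control rats, 8 weeks after streptozotocin or buffer, on arrays that measure protein-coding and long non-coding transcripts. The question is which coding and non-coding RNAs differ in the ganglia of diabetic rats. Signals ran from 1.75 to 19.9 on the log2 scale, with array medians of 3.95 to 4.15. Exon control probe sets outranked intron controls with an area under the curve of 0.918 to 0.929 in 5 arrays and 0.902 in control replicate 3.

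The arrays resembled each other closely, and the groups did not separate. Pearson's correlation between arrays lay between 0.993 and 0.997 across 68842 transcript clusters. Its mean was 0.9962 within groups and 0.9956 between them. The first principal component took 40.0% of the variance and set control replicate 3 apart, at -57.9, while the other arrays lay between -13.8 and 35.3. Diabetic replicate 2 lay beside control replicates 1 and 2.

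**Figure D1:**
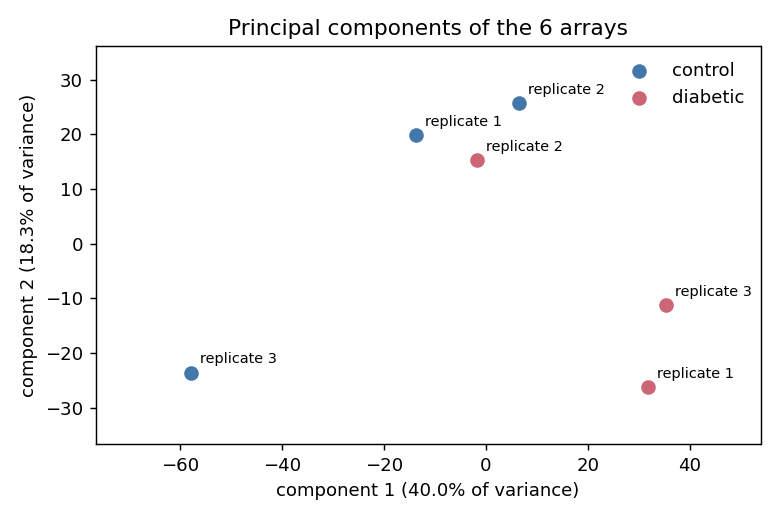
Scores of the 6 arrays on the first and second principal component of the log2 signals, with the share of variance on each axis. Blue points are control and red points diabetic arrays; control replicate 3 lies at -57.9 on the first component and diabetic replicate 2 lies near control replicates 1 and 2.

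In diabetic ganglia, 4 transcripts passed adjusted p 0.05 among 68842 tested: 3 were higher and 1 was lower. Reg3b, a secreted C-type lectin known from the pancreas and from injured nerve, rose 24.8-fold, from 5.21 ± 0.48 to 9.84 ± 0.81 (log2, SD, n = 3 per group, adjusted p = 0.035 in limma). Its neighbour Reg3a rose 5.95-fold, from 5.11 ± 0.20 to 7.68 ± 0.26 (SD, n = 3, limma adjusted p = 0.0053). Both lie on chromosome 4, Reg3b at 109467272 to 109470510 and Reg3a at 109477893 to 109480661, on the plus strand. Reg3g, a further member of the family, was at 3.21 in controls and 3.29 in diabetic ganglia. Cross-hybridisation between Reg3 genes was not tested. Control signals of Reg3a and Reg3b, like diabetic signals of Csn1s1, lay below the 90th percentile of the intron controls (6.06 to 6.67 per array). These folds thus set a signal against background. They may understate the change, but sampling error goes both ways, so they are estimates and not bounds.

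The largest fall among these was that of Csn1s1, which encodes the milk protein alpha-s1 casein. Its signal was 8.12-fold lower, at 4.81 ± 0.23 against 7.83 ± 0.05 (SD, n = 3, limma adjusted p = 0.00057). It lies on the minus strand of chromosome 14, at 21993450 to 22009308. A short transcript without a gene assignment, V-set.69 on chromosome 3 at 19552864 to 19553384, was at 3.40 ± 0.11 in controls and 4.64 ± 0.16 in diabetic ganglia (SD, n = 3; adjusted p = 0.049). Both signals lay below the 90th percentile of the intron controls, so no fold is given. With each array left out in turn, Csn1s1 passed in 6 of 6 fits and Reg3a in 5, missing only without control replicate 2 (adjusted p = 0.065). Reg3b passed in 1 fit, the one without diabetic replicate 2 (adjusted p = 0.024, otherwise 0.091 to 0.24), and V-set.69 in 0 (adjusted p = 0.14 to 0.30). V-set.69 also missed without the trend (adjusted p = 0.065), with robust estimation (0.052) and with the replicate number as a block (0.10). Without moderation of the variance 0 of the 4 passed (adjusted p = 0.40 to 0.77), and Reg3b did not pass with the filter at the median level (adjusted p = 0.053).

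**Figure D2:**
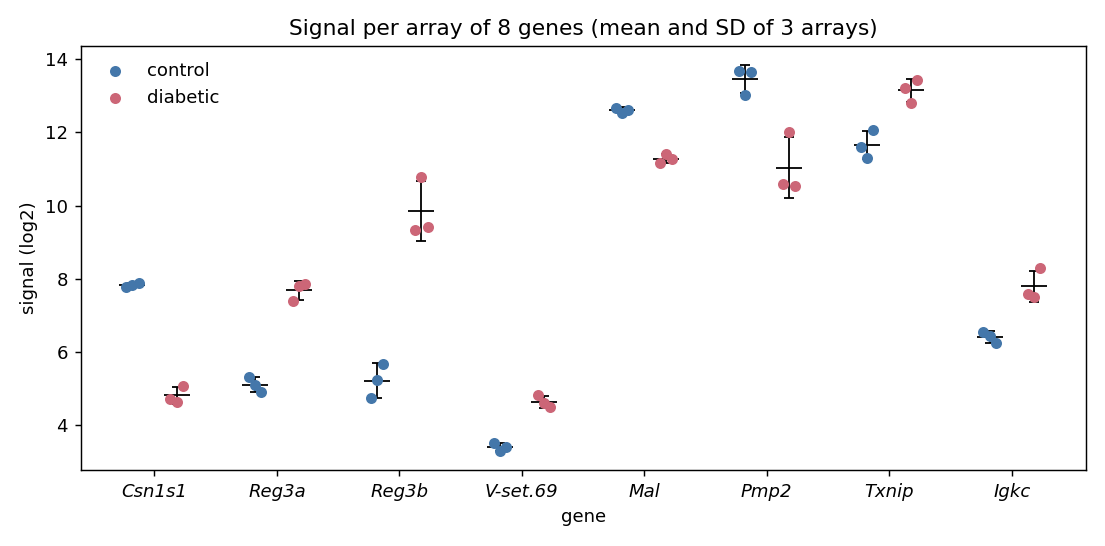
Log2 signal of 8 genes in each array, blue for control and red for diabetic, with the mean and SD of 3 arrays in black. Reg3a, Reg3b, Csn1s1 and V-set.69 passed adjusted p 0.05. Mal, Pmp2, Txnip and Igkc did not pass and were chosen among genes without overlap between the groups.

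The coding genes next in rank did not pass the adjusted threshold. They were ranked only among clusters of at least 1.5-fold without overlap between the groups' arrays. Their lack of overlap is therefore a condition of the choice and no evidence for them. Over all clusters 13.3% showed no overlap, where chance gives 10%. Lower in diabetic ganglia were Mal, a myelin proteolipid (log2 fold change -1.32, SE 0.13, adjusted p = 0.057), Pmp2, the fatty acid binding protein of peripheral myelin (-2.42, SE 0.38, adjusted p = 0.50), and Ermn, a myelin-associated cytoskeletal protein (-1.29, SE 0.17, adjusted p = 0.41). Also lower were Fa2h, which hydroxylates myelin lipids (-0.78), the Schwann cell claudin Cldn19 (-0.87), gliomedin Gldn of the node of Ranvier (-0.84) and Padi2, a peptidylarginine deiminase (-1.09). Outside myelin the lowest ranked were Thbs4 (-0.88), Chrdl1, a BMP antagonist (-0.82), and, below the 90th percentile of the intron controls in both groups, Epyc (5.14 and 4.31) and the muscle M-band gene Myom2 (5.86 and 4.86). Their adjusted p lay between 0.41 and 0.50 apart from that of Mal.

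Higher without passing were Txnip, the thioredoxin inhibitor whose transcription follows glucose (11.65 ± 0.39 to 13.15 ± 0.32, SD, n = 3, or 2.83-fold), the immunoglobulin light chain gene Igkc (2.61-fold) and the RNA-binding protein gene Rbm3 (2.52-fold). Smaller differences were those of Ggt5 (log2 fold change 0.97), Hist2h2ab (0.96), the predicted ribosomal gene RGD1565317 (0.78), Med22 in both of its clusters (5.30 and 6.09, 5.30 and 6.03), the histamine receptor Hrh1 (4.40 and 5.09) and the adenosine receptor Adora2b (4.80 and 5.44). Hrh1 and Adora2b lay below the 90th percentile of the intron controls in both groups. For these 9 genes the adjusted p was 0.497 to 0.505. Pmp2 passed without diabetic replicate 2 (-2.90, adjusted p = 0.037). Mal passed without the intensity trend (adjusted p = 0.029), with array weights (0.032) and after quantile normalization (0.039), and its adjusted p over all alternatives ranged from 0.029 to 0.69.

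By the looser criterion, 684 clusters differed by 1.5-fold or more at an unadjusted p under 0.05, 258 higher and 426 lower. Coding clusters gave 142 higher and 143 lower, but 261 and 96 after median centring and 383 and 230 without diabetic replicate 2. For all clusters, centring each array on its median turned the split to 480 higher and 295 lower. Without control replicate 2 the count was 1442, without diabetic replicate 2 it was 1444, and without diabetic replicate 1 it split into 290 higher and 283 lower.

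No non-coding cluster passed adjusted p 0.05 in limma, of 25625 tested, and 0 passed under any alternative fit. At an unadjusted p under 0.05 there were 1824, of which 262 were higher and 1562 lower. This imbalance depends on the scaling of the arrays: 71.5% of all non-coding clusters had a lower mean, but 48.4% after median centring. The non-coding transcripts of highest rank among those higher in diabetic ganglia were LOC102551204 on chromosome 12 (22680635 to 22685582, 4.96 to 6.13), LOC102549182 on chromosome 3 (6.55 to 7.73), ENSMUSG00000088069 (6.45 to 7.65), NONMMUG023347 (6.95 to 7.72) and NONMMUG027336 (5.62 to 6.28), the last names being those of mouse transcripts placed on the rat genome. NONMMUG027336 lies at 198685642 to 198686971 on the minus strand of chromosome 2, antisense to the end of Txnip at 198682946 to 198686975. Among those lower were uc029rak.1, a short locus on chromosome 7 measured by 1 probe (6.33 to 4.28), and uc007glo.1, measured by 7 probes (3.44 to 2.31). Also lower were NONMMUG003580 (6.34 to 5.27), a locus on chromosome 4 at 29564290 to 29571817 (7.16 to 6.12) and an unnamed locus on chromosome 18 at 29647839 to 29647979 (log2 fold change -0.98). Signals of uc007glo.1 lay below the medians of the intron controls (3.95 to 4.21), and control signals of LOC102551204 below their 90th percentile. The limma adjusted p of the non-coding transcripts named here lay between 0.41 and 0.53.

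Non-coding clusters as a class lay slightly lower in diabetic ganglia, with 71.5% of them lower and a median log2 fold change of -0.07, against 50.5% and 0.00 for coding clusters. The 1153 intron control probe sets, which mark background, also lay lower, with a median of -0.11. Centring the arrays on their medians ended this, at 48.4% lower, and quantile normalization gave 52.2%. Coding clusters passed the looser criterion more often than non-coding clusters, 285 of 24753 (1.15%) against 87 of 25625 (0.34%). The non-coding count, 24 higher and 63 lower, ran from 19 to 54 higher and from 57 to 217 lower with an array left out. The odds ratio was 3.42 (95% interval 2.68 to 4.40; Fisher's exact test over clusters, two-sided, p = 1.9e-27), and 1.74 without control replicate 1. Non-coding clusters were dimmer, with a median level of 3.58 against 5.34. Within bands of equal level the excess was gone: in the brightest band 2.03% of coding and 2.90% of non-coding clusters passed, an odds ratio of 0.69 (0.52 to 0.94, Fisher's exact p = 0.016), and in the middle band 0.92 (0.42 to 1.93).

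Fold changes of neighbouring non-coding and coding transcripts were weakly related. Across 16008 pairs within 10 kb, Spearman's rho was 0.058, against a highest value of 0.030 in 10000 random pairings (permutation p = 0.0001, the smallest they can give, adjusted p = 0.00015 over 6 relations). Pairs overlapping on opposite strands gave 0.089 (7335 pairs, permutation p = 0.0001, adjusted 0.00015) and pairs without overlap 0.072 (4173 pairs, permutation p = 0.0001, adjusted 0.00015). Overlapping pairs on the same strand, which can share probes, gave -0.012 (4500 pairs, permutation p = 0.437, adjusted 0.437). Where both clusters lay above the median level, rho over all pairs was 0.11 (3757 pairs). The relation is across genes, which are not independent replicates. Random pairing breaks only the adjacency of genes, so these p-values do not test diabetic against control. Of 10 splits of the 6 arrays into 3 and 3, 5 gave a rho as high, the real split included, with up to 0.070.

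Genes of myelinating Schwann cells, the glia that wrap sensory axons, were lower as a group. Of 20 measured, 19 had a lower mean in diabetic ganglia, the median log2 fold change was -0.52, and 14 fell past adjusted p 0.05 over the list alone, while 0 passed over all clusters. Besides Mal, Fa2h, Cldn19 and Gldn, all past the list threshold, the myelin protein gene Pmp22 was at 15.70 and 15.58, not past it. Egr2, the transcription factor of myelination, was at 7.84 and 7.91. Camera gave an adjusted p of 5.3e-17 with the preset correlation and an adjusted p of 0.39 with an estimated correlation of 0.45 between members. With any 1 array left out the list stayed past the threshold at the preset correlation.

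Matrix genes were lower beside them. In the fibroblast and extracellular matrix list 19 of 28 had a lower mean (median -0.25) and 9 fell past adjusted p 0.05 over the list alone, led by the fibrillar collagen genes Col1a1 (log2 fold change -2.02, SE 0.36), Col3a1 (-1.77, SE 0.36), Col1a2 (-1.59, SE 0.29) and Col5a2 (-0.63, SE 0.15). Of its most abundant genes, Sparc was lower by 0.54 (0.34 without diabetic replicate 1) and Dcn was at 15.77 and 16.02. Camera gave an adjusted p of 0.0099, or an adjusted p of 0.68 with an estimated correlation, and the list no longer passed without control replicate 1 (adjusted p = 0.26) or diabetic replicate 1 (adjusted p = 0.065); its median was -0.06 without diabetic replicate 1, -0.16 without control replicate 3 and -0.39 without control replicate 2. All 17 basement membrane genes had lower means (median -0.22, camera adjusted p = 0.00049, and adjusted p = 0.65 with an estimated correlation), among them Nid1 (-0.99), Lama2 (-0.85), Lamb1 (-0.47, and -0.26 without diabetic replicate 1) and Nid2 (-0.33), with 0 past the threshold over the list alone and a median of -0.09 without diabetic replicate 1. All 23 skeletal muscle genes also had lower means (median -0.33, camera adjusted p = 0.00072, and adjusted p = 0.68 with an estimated correlation), with Mb at 5.01 and 4.36, Casq1 at 4.70 and 4.30 and Acta1 at 7.59 and 7.26. The median level of the muscle genes, 4.61, lay below the 90th percentile of the intron controls, which themselves had a median log2 fold change of -0.11. Without control replicate 2 the muscle median was -0.05 (adjusted p = 0.70) and Acta1 was higher by 0.40, and without control replicate 1 it was -0.53.

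**Figure D3:**
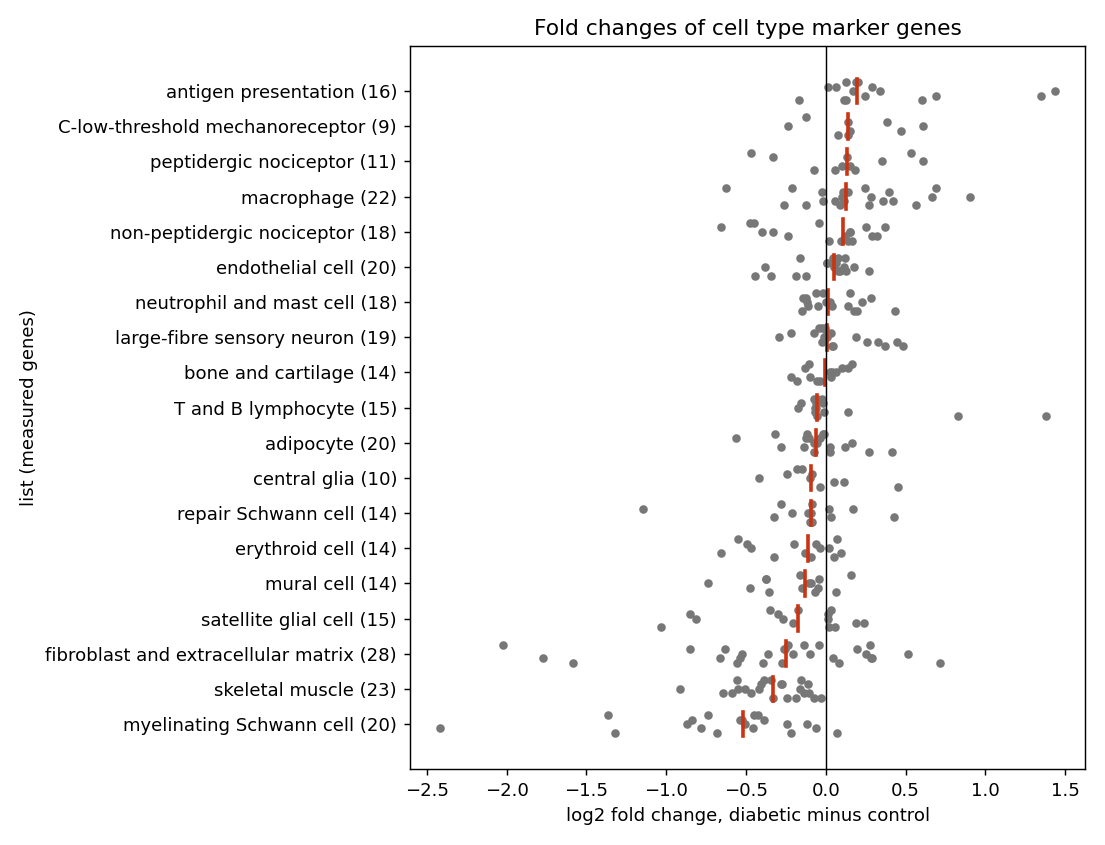
Log2 fold change, diabetic minus control, of each measured gene of the cell type lists (grey points) with the median of each list (red bar) and the number of genes in brackets. The myelinating Schwann cell list has the lowest median, -0.52, and antigen presentation the highest, 0.20.

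The lists of nociceptor genes did not pass camera. In the peptidergic nociceptor list 8 of 11 had higher and 3 lower means (median 0.13, camera adjusted p = 0.14). The peptidergic nociceptor list passed without control replicate 2 (median 0.16, adjusted p = 0.024) and without diabetic replicate 2 (median 0.28, adjusted p = 0.0059), and its median was 0.02 without diabetic replicate 1. The neuropeptide gene Calca was at 12.60 ± 0.17 and 12.70 ± 0.15 and Tac1 at 13.09 ± 0.15 and 12.76 ± 0.19 (SD, n = 3), and the log2 fold change of the irritant channel gene Trpa1 was -0.47. In the non-peptidergic list (median 0.11, camera adjusted p = 0.39, median -0.06 without control replicate 3) Mrgprx3 fell by 0.66, past adjusted p 0.05 over the list alone, and Ret was at 15.28 and 15.23 and Cd55 at 15.70 and 15.82. The pain channel genes Scn9a (13.62 and 13.64), Scn10a (14.13 and 14.08) and Trpv1 (10.33 and 10.39) differed by less than their spread, as did Nefh (18.95 and 18.92). C-fibre low-threshold mechanoreceptor genes were higher in 7 of 9 (median 0.14, camera adjusted p = 0.00057, and adjusted p = 0.55 with an estimated correlation), with Th (4.55 and 5.16) and Tafa4 (5.82 and 6.29) past the threshold over the list alone; the median was 0.09 without diabetic replicate 3 and 0.23 without diabetic replicate 2. Large-fibre genes had a median of 0.01 (camera adjusted p = 0.037, and adjusted p = 0.68 with an estimated correlation), with Runx3 at 5.48 and 5.97 and Nefl at 18.72 and 18.76, and lost the call without control replicate 1, control replicate 3 or diabetic replicate 3 (adjusted p = 0.12, 0.28 and 0.68, median 0.006, 0.03 and -0.003). Without control replicate 2 or diabetic replicate 2 their median was 0.06 and 0.05.

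Excitability and synapse genes were mostly slightly higher, and their camera calls were lost with an estimated correlation. Sodium channel genes were higher in 15 of 17 (median 0.09, camera adjusted p = 0.0013, and adjusted p = 0.65 with an estimated correlation), with the subunits Scn4b (0.69) and Scn3b (0.46) leading. Medians were 0.03 for potassium channels (camera adjusted p = 0.0042), 0.10 for calcium channel and HCN genes (0.0029), 0.21 for synaptic vesicle genes (1.5e-06) and 0.14 for cytoskeleton and axonal transport genes (0.00015), each with an adjusted p = 0.68 with an estimated correlation. In these 5 lists 0 genes passed over the list alone. General neuronal genes, a list added after the results were seen, had higher means in 13 of 13 (median 0.17, and 0.09 without control replicate 3). Leaving out that array turned Tubb3, Avil, Scn9a and Elavl3 lower. Without control replicate 3 the sodium, potassium and calcium channel and cytoskeleton lists did not pass (adjusted p = 0.15, 0.39, 0.22 and 0.41), nor did the potassium and calcium lists (0.15 and 0.41) and the cytoskeleton list (median 0.06) without diabetic replicate 3 or the potassium and calcium lists without diabetic replicate 1 (0.098 and 0.051). Over the 6 fits with an array left out, the lowest medians came without control replicate 3 or diabetic replicate 1 or 3 and the highest without control replicate 2 or diabetic replicate 2: 0.03 to 0.17 for sodium, 0.01 to 0.16 for potassium and 0.02 to 0.26 for calcium channels, 0.13 to 0.35 for vesicle and 0.05 to 0.25 for cytoskeleton genes.

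TRP, ASIC, P2X and Piezo channel genes (median 0.01, camera adjusted p = 0.82) and opioid, GABA and glutamate receptor genes (0.01, adjusted p = 0.30) had medians near 0. Both passed without diabetic replicate 2 (median 0.04 and 0.03, adjusted p = 0.049 and 0.015), and the lowest median was -0.05 for TRP, ASIC, P2X and Piezo channels, without control replicate 3, and -0.02 for the receptors, without diabetic replicate 1. The purine receptor genes P2rx2 and P2rx7 gave log2 fold changes of 0.64 and -0.47, the serotonin receptor gene Htr3b was at 13.65 and 14.18, and the kainate receptor gene Grik2 at 9.79 and 8.82.

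Injury genes other than the Reg3 pair differed little. The axon injury and regeneration list was higher in 31 of 39 (median 0.11, camera adjusted p = 1.8e-06, and adjusted p = 0.23 with an estimated correlation), and only Reg3a and Reg3b passed over the list alone. Its median was 0.07 without diabetic replicate 3. The injury transcription factor Atf3 was at 4.79 ± 0.11 and 4.82 ± 0.01, galanin (Gal) at 6.13 ± 0.10 and 6.13 ± 0.39 and Npy at 5.46 ± 0.17 and 5.55 ± 0.45 (SD, n = 3). Sox11 was at 5.79 and 6.15 and Stmn4 at 5.70 and 6.08. Neurotrophic signalling genes had a median of 0.02 (camera adjusted p = 0.034, and adjusted p = 0.58 with an estimated correlation), with Cntf at 9.68 and 9.04 and Insr at 6.79 and 7.23. Of the 6 fits with an array left out, they passed in 2, without control replicate 2 or diabetic replicate 2 (median 0.07 and 0.08). Without control replicate 1 their median was -0.006 (adjusted p = 0.12). Without control replicate 3 and diabetic replicates 1 and 3 the adjusted p was 0.25, 0.10 and 0.37.

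Stress hormone and early response genes were higher. Of 19 glucocorticoid response genes 15 had a higher mean (median 0.27, camera adjusted p = 1e-07, and adjusted p = 0.55 with an estimated correlation), and 6 rose past adjusted p 0.05 over the list alone, among them Dusp1 (0.87), Nfkbia (0.62), Cebpd (0.61) and Per1 (0.54). Immediate early genes were higher in 21 of 26 (median 0.07, adjusted p = 2.9e-05, and adjusted p = 0.39 with an estimated correlation), with Ier2 (0.98), Dusp1 and Junb (3.91 and 4.42) past the list threshold. Circadian clock genes had a median of 0.05 (adjusted p = 0.00066, and adjusted p = 0.35 with an estimated correlation), with Per1 and Bhlhe40 (0.52) past it. Ribosomal protein genes were higher in 50 of 55 (median 0.15, adjusted p = 3e-12, and adjusted p = 0.58 with an estimated correlation), with 0 past the list threshold. The ribosomal median was 0.06 without control replicate 2 and 0.25 without control replicate 3. Without diabetic replicate 3 the glucocorticoid median was 0.15 and the immediate early median 0.04, the latter being 0.11 and 0.12 without diabetic replicates 1 and 2. Cell cycle genes (median -0.09, adjusted p = 0.068) included Top2a at 4.50 and 4.04, and passed in 5 of 19 alternatives: without diabetic replicate 2, with array weights, with the filter at the median level, with the mean of a symbol's clusters and with coding symbols only (adjusted p = 0.0014, the lowest). ER stress and heat shock genes (median -0.05, 0.004 without control replicate 1, adjusted p = 0.82) held Hsph1 and Cryab, which fell by 0.89 and 0.87 past the list threshold.

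Among metabolic lists, glycolysis and pentose phosphate genes were higher in 29 of 35 (median 0.14, camera adjusted p = 2.9e-07, and adjusted p = 0.57 with an estimated correlation), of which only Txnip passed over the list alone. Oxidative phosphorylation genes had a median of 0.08 (adjusted p = 1.2e-05, and adjusted p = 0.58 with an estimated correlation). Fatty acid oxidation and ketogenesis genes had 0.04 (adjusted p = 0.016, and adjusted p = 0.39 with an estimated correlation), with Pdk4 at 5.81 and 6.55. NRF2 and antioxidant genes had 0.03 (adjusted p = 0.0027, and adjusted p = 0.57 with an estimated correlation), with Mt2A at 11.94 and 12.52. Fatty acid oxidation did not pass without control replicate 3 or diabetic replicate 3 (adjusted p = 0.059 and 0.14, median 0.02 in each), and its median was -0.003 without control replicate 2. The NRF2 list did not pass without control replicate 2 (adjusted p = 0.058), and its median was 0.05 without control replicate 1 or 3 and 0.04 without diabetic replicate 2. Without control replicates 2 and 3 the medians were 0.21 and 0.06 for glycolysis and 0.05 and 0.12 for oxidative phosphorylation. Fatty acid synthesis genes were lower in 15 of 24 (median -0.11, adjusted p = 0.056). They passed in 7 of 19 alternatives, among them quantile normalization (adjusted p = 0.0012), median centring, and the fits without control replicate 3 (median -0.15) or diabetic replicate 3 (adjusted p = 0.0056). In this list were the elongase gene Elovl6, lower by 0.77, past the list threshold, and Scd, at 13.51 and 12.92. Cholesterol synthesis genes (median -0.03, 0.05 without control replicate 2, adjusted p = 0.94) held Idi1 at 11.50 and 11.02. In the polyol, hexosamine and glycation list (median -0.03, 0.04 without diabetic replicate 2, adjusted p = 0.31) Oga, the enzyme that removes O-GlcNAc, was higher by 0.83, past the list threshold. The insulin genes Ins1 (4.28 and 3.97) and Ins2 (5.97 and 5.74) and the glucose transporter gene Slc2a4 (4.34 and 4.26) did not pass.

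Immune lists gave mixed values. Antigen presentation genes were higher in 15 of 16 (median 0.20, camera adjusted p = 1.2e-07, and adjusted p = 0.39 with an estimated correlation), with the class II genes RT1-DMa (0.60, past the list threshold), Cd74 (1.35, SE 0.40) and RT1-Da (1.44, SE 0.54, and 0.82 without control replicate 2). Macrophage genes had a median of 0.13 (adjusted p = 0.00039, and adjusted p = 0.68 with an estimated correlation), with the scavenger receptor gene Cd163 higher by 0.90, past the list threshold, and C1qa at 8.87 and 9.15, but the median was -0.01 without control replicate 2 (adjusted p = 0.70). It was 0.31, 0.29 and 0.25 without control replicates 1 and 3 and diabetic replicate 1, and 0.06 without diabetic replicate 2. In the complement list (median 0.04, adjusted p = 0.052) C5ar1 was higher, at 5.01 in diabetic ganglia and below the 90th percentile of the intron controls in both groups, past the list threshold, and A2m was at 8.98 and 7.64. The complement and coagulation list passed without control replicate 1 (median 0.11, adjusted p = 0.00014), diabetic replicate 1 (0.0056) or diabetic replicate 3 (0.036), and its median was -0.08 without control replicate 2 and -0.01 without diabetic replicate 2. Lymphocyte genes (median -0.06, adjusted p = 0.61) held Igkc past the list threshold and Cd4 at 7.59 and 8.42. Cytokine genes (-0.02, adjusted p = 0.30), interferon response genes (-0.05, adjusted p = 0.35) and neutrophil and mast cell genes (0.01, adjusted p = 0.31) did not pass, with Tgfb1 at 5.58 and 6.25, Ifit1 at 6.29 and 5.53 and Lcn2 at 6.00 and 6.22. Without control replicate 3 the cytokine median was 0.03 and the interferon median 0.002. The interferon list passed without diabetic replicate 2, after quantile normalization and with coding symbols only (adjusted p = 0.038, the lowest), and the neutrophil list without diabetic replicate 3 (adjusted p = 0.044), its median being -0.06 without control replicate 2.

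The remaining cell type lists did not pass camera. Satellite glial genes had a median of -0.18 (adjusted p = 0.31), with the potassium channel gene Kcnj10 (-0.85) and Ptprz1 (-1.04) past the list threshold and the abundant Glul (14.36 and 14.55) and Apoe (13.79 and 13.85) not. The satellite glial median was 0.009 without control replicate 3, and the list passed without diabetic replicate 3 (adjusted p = 0.044). Medians were -0.09 for repair Schwann cell genes (adjusted p = 0.33, with Tyrp1 at 17.30 and 16.15), -0.13 for mural cells (adjusted p = 0.10), 0.05 for endothelium (adjusted p = 0.37) and -0.06 for adipocytes (adjusted p = 0.58, with Gpd1 at 7.86 and 7.30 past the list threshold). They were -0.11 for erythroid genes (adjusted p = 0.37, with Hba-a2 at 15.75 and 15.09), -0.09 for central glia (adjusted p = 0.63), -0.005 for bone and cartilage (adjusted p = 0.82) and -0.07 for named long non-coding RNAs (adjusted p = 0.32), of which Snhg11 was at 9.51 and 8.92 and Dleu2 at 4.45 and 4.18. The mural list passed without control replicate 2 (median -0.19, adjusted p = 0.0068) or diabetic replicate 3 and with array weights, quantile normalization or coding symbols only, its median being -0.07 without control replicate 1, and the erythroid list without diabetic replicate 2 (adjusted p = 0.0017). The erythroid median was -0.23 without control replicate 2 and -0.06 without control replicate 1. Without control replicate 2 the medians were -0.008 for named long non-coding RNAs and -0.04 for bone and cartilage, and without control replicate 3 they were -0.04 for central glia, -0.02 for adipocytes and -0.06 for repair Schwann cell genes. The endothelial list passed without diabetic replicate 1 (adjusted p = 0.017), and its median was -0.05 without control replicate 2. After quantile normalization the large-fibre, potassium, calcium, neurotrophic, fatty acid oxidation, oxidative phosphorylation and NRF2 lists did not pass, nor did these, apart from oxidative phosphorylation, with the filter at the median level. After median centring the large-fibre and neurotrophic lists did not pass. With coding symbols only the large-fibre, sodium (adjusted p = 0.052), potassium, calcium, neurotrophic, fatty acid oxidation and NRF2 lists did not pass. In all, camera called 23 of 46 lists with the preset correlation, 19 higher and 4 lower, and 0 with an estimated correlation. Camera ranked the cytokine, polyol, lymphocyte, bone, ER stress and cholesterol lists as higher although their medians were under 0, and the endothelial, non-peptidergic and TRP lists had means under 0 with medians above it. Each list is set against all other symbols, and over all 68842 clusters 61.8% were lower, with a median log2 fold change of -0.04. A list near 0 can therefore rank as higher, and an upward call need not be a rise of its genes. Fry called 0 for a common direction and 13 for change in either direction.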

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

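Chosen after the results were seen were the comparison of lists with coding symbols only (20 lists called against 23, 16 of them shared), the share of non-coding clusters with a lower mean, and, for the coding share and the neighbour correlation, the variance, weight, normalization and block settings. Fits without the trend, with robust estimation and with the series matrix values kept each count of clusters within 1.5 times. Their list calls, like those without moderation of the variance, could not change. Camera does not use the eBayes settings, and the series matrix holds the same numbers. These settings are still counted among the alternatives given for the cell cycle and fatty acid synthesis lists. Without moderation of the variance 0 clusters passed adjusted p 0.05 (0 coding), and the 1.5-fold count was 371. With the filter at the median level 2 clusters passed. At 2-fold in place of 1.5-fold 71 clusters were counted. With an estimated correlation, and with fry, 0 lists passed. With each array left out, 1 to 5 clusters passed (1 to 4 of them coding, 0 non-coding), the 1.5-fold count ran from 556 without control replicate 3 to 1444 without diabetic replicate 2, 17 to 29 lists were called, and the odds ratio of coding against non-coding changes ran from 1.74 to 3.12. With adjusted p 0.05 as the criterion the odds ratio, with 0.5 added to each count, was 7.25 and no longer past its threshold (Fisher's exact p = 0.12), since 3 coding and 0 non-coding clusters passed. The share of non-coding clusters with a lower mean, 71.5%, was 52.2% after quantile normalization again, 48.4% after median centring and 60.4% to 74.7% with an array left out. Of the lists called, 4 medians changed sign when an array was left out: large-fibre neuron (-0.0029 without diabetic replicate 3, up to 0.0563), macrophage (-0.0109 without control replicate 2, up to 0.305), neurotrophic signalling (-0.0062 without control replicate 1, up to 0.0824) and fatty acid oxidation (-0.0028 without control replicate 2, up to 0.0315). Over all alternatives, lists changed sign without passing in 42 cases and genes in 44. The cause was not tested. With the replicate number as a block 3 clusters passed and 25 lists were called. Deviations of same-numbered arrays correlated at 0.04, -0.18 and -0.18, and no array correlated best with its own number. These values showed no pairing of the animals by number, but so few arrays cannot exclude one. The similarity within groups exceeded that between groups by 0.0006, and by 0.0001 to 0.0013 with an array left out. Signal over background limits the dim clusters, whose levels lie near those of the intron controls, at medians of 3.95 to 4.21.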

Other observations

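The tests of a smaller share of Schwann cells, of neuronal RNA and of control replicate 3 for the myelin list, and of axon injury and of a single animal for the Reg3 genes, were chosen only after those results were seen. The 5 gene lists used here beyond the fixed ones were added after the main results were seen. All 13 measured pan-neuronal genes had higher means in diabetic ganglia, with a median log2 fold change of 0.17 (95% bootstrap interval 0.12 to 0.31). Bootstrap intervals in this section resample the genes of a list, not the animals, so they do not give the spread between animals. Among the genes were the transcription factor gene Isl1 (0.43, and 0.39 without control replicate 3) and Eno2 (0.53, and 0.32 without it). Without that array the median was 0.09, and Tubb3 (-0.07), Avil (-0.02), Scn9a (-0.12) and Elavl3 (-0.03) were lower. Camera gave an adjusted p of 8.4e-06 with the preset correlation and an adjusted p of 0.52 with an estimated correlation, and 0 genes passed over the list alone. Plasma cell genes, tested because Igkc was higher, had 3 higher and 6 lower of 9 (median -0.08, adjusted p = 0.91), with Xbp1 at 0.16 and Sdc1 at 0.20. Of 10 genes of fibrillar and fibril-associated collagens 9 had lower means (median -0.45), which is no separate test, since Col1a1, Col1a2, Col3a1 and Col5a2 had been seen to be lower when the list was written.

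The lower myelin genes were weighed first. A larger share of neuronal RNA would lower the markers of all other cells alike. The endothelial list had a median of 0.050 (95% bootstrap interval -0.06 to 0.08) against -0.52 (-0.76 to -0.41) for myelin. This argues against such a share as the only source of the lower myelin genes. Other non-neuronal lists went both ways, with medians of -0.25 for fibroblasts, -0.18 for satellite glia, -0.13 for mural cells and 0.13 for macrophages. A smaller contribution of neuronal RNA therefore stays open. The array of control replicate 3 is argued against too, as the myelin median was -0.56 without it, with 19 of 20 genes lower and 14 at an unadjusted p under 0.05. A smaller share of myelinating Schwann cells stays open: the SD of the members' changes was 4.31 times their median standard error (16 genes, 95% bootstrap interval 1.98 to 5.83), above the bound of 2 set for a common shift, but the interval includes 2. Reduced transcription of myelin genes in the diabetic animals may also account for it and was not tested.

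For the collagen genes, the array of control replicate 3 is argued against, since their median was -0.46 without it and -0.45 with all arrays. Less connective tissue could not be decided: 13 other fibroblast genes had a median of 0.046 (95% bootstrap interval -0.26 to 0.22), 7 of them higher and 6 lower, whose interval overlaps the -1.59 to -0.20 of the collagens. Overlap had been named beforehand as fitting this explanation, and the criterion was made stricter after the values were seen, because the median lies near 0 and the genes go both ways. A difference in collagen transcription in diabetic animals may remain as an explanation.

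For Reg3a and Reg3b, carry-over of pancreatic RNA is argued against: 14 acinar enzyme genes had a median of -0.075, and 0 of them lay above the 90th percentile of the intron controls in the diabetic arrays, 6.00. The rise was seen in every diabetic array, the lowest lying 2.06 log2 units above the highest control array for Reg3a and 3.65 for Reg3b. Both genes were named for passing without overlap between the groups. The gaps therefore describe the rise and are no separate test of a rise in 1 animal. Injury of axons stays open: the 36 injury genes other than Reg3a, Reg3b and Reg3g had a median of 0.10 (95% bootstrap interval 0.03 to 0.16), with 28 higher and Atf3 at 0.02, where the criterion first written, an interval under 0.5, would have argued against it, and it was made stricter after the values were seen because members go both ways.

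There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05, and the real split is counted among those below. The real split called 4 clusters at adjusted p 0.05 and the highest other split 2, so 1 split gave as many. For the 1.5-fold count, 2 splits gave as many as 684, the highest other giving 813, when control replicates 1 and 3 stood with diabetic replicate 2. For gene lists, 4 splits gave as many as 23, with up to 31. For the odds ratio of coding against non-coding changes 2 splits lay as far from 1, the other at 4.80 against 3.42. For the neighbour correlation 5 splits gave as much as 0.058, with up to 0.070. Among 1738 control probe sets, 0 passed adjusted p 0.05 in limma and 133 had an unadjusted p under 0.05.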
